A study of Homo sapiens with 2 samples.

How the data were processed

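Exosomes were collected from HuH-7 cultures, per the labels' protocols, after growth in medium with 10% fetal bovine serum and a change to advanced DMEM, by filtration and ultracentrifugation at 110000 g for 70 min at 4 °C. Extracted RNA was labelled with Cy5 using the labelling kit of the 3D-Gene miRNA platform and hybridised to 1 array per culture. There were 2 samples, HuH-7-P exosome and HuH-7-M exosome, each grouped by its title, with n = 1 per group. No label states whether the cultures or labelling reactions differed in day, and 1 array per group leaves any such batch inseparable from the cultures.

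The deposited scanner output of each array lists 3200 spots with, per the file headers, a spot median intensity in the Cy5 channel and a second intensity column named as background median. No background had been subtracted from the spot median. The spots comprise 2565 miRNA probes with 1 spot each, 320 BLANK spots, 85 spots labelled No Probe, and negative, spike and other control probes. The detection-like entries of the files did not separate probes from BLANK spots and were not used; 2 probes of the HuH-7-M array carried a bad-spot entry and were kept. miRNA names are those of the array design.

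The authors also deposited a table of intensity values for 2552 miRNA identifiers. The values of all rows but 2 could be rebuilt from the scanner output and matched to 1 probe each, to a relative tolerance of 1e-06, as the spot median minus the mean of the BLANK spots (top and bottom 5% left out), left blank where the spot did not exceed that mean plus 2 SD, divided by the median of these differences over all miRNA probes above that limit (30.5 on HuH-7-P and 29.8 on HuH-7-M) and multiplied by 25. For 8 probes above the limit, miR-3960 among them, no row matched in both values. The table gives 1663 values for each array, against 1669 probes above the limit on HuH-7-P and 1671 on HuH-7-M, so its own medians need not be 25. The scale is linear, and the column medians were 24.9 for HuH-7-P and 24.8 for HuH-7-M. The software that made it is not given in the sources used here. Matched by value to the scanner output, 699 of 1739 matched rows carried the name that the scanner output gives for that value and 1040 carried another name. Before table row 1134 the names agreed in every matched row, and from there on in none, with 1037 of the names off by exactly 2 rows. The files do not state which source names the probes correctly, so a check was added after seeing the data. miRNAs on the same arm whose names differ by a letter only have related sequences, and their signals should lie close together under the right names. From row 1134 on, the median gap within such pairs in the authors' values was 0.86 (log2) under the scanner's names, over 33 pairs in 19 families, at the 0.20th percentile of 2000 random draws. Under the table's names it was 3.51 over 24 pairs in 15 families, at the 97.1st percentile. Before that row it was 0.95 over 61 pairs, at the 0.050th percentile. This argues for the scanner's names, which are used throughout; the identity of miRNAs such as miR-5580-3p and miR-4732-5p rests on that choice. Here each value of this table was assigned to the probe it was rebuilt from, and the names as given were tried as an alternative. miR-638, miR-663a, miR-3648 and miR-4258 had the same values under both assignments.

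The analysis used the spot median intensity. The plan fixed before the data were examined asked for normexp background correction with the local background where the scanner output gives one. The column named as background did not behave as a local background. Its logarithm correlated across miRNA probes with that of the spot median at r = 0.992 on HuH-7-P and 0.992 on HuH-7-M, and it exceeded the spot's own signal at 21.8% and 16.3% of the miRNA spots. The plan's next branch was therefore used as the main setting, namely normexp fitted on the BLANK spots as negative controls (nec in limma 3.58.1, R 4.3.3) with an offset of 50, followed by quantile normalization over the miRNA probes and log2. The plan read to the letter is kept as an alternative chosen after seeing the data. The offset of 50 pulls differences of dim probes toward 0, so log2 differences understate fold differences near background.

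A miRNA was called above background where its spot median exceeded the mean plus 2 SD of the BLANK spots after leaving out their top and bottom 5%, and measured where this held on both arrays. The stricter No Probe limit, 86.9 on HuH-7-P and 89.9 on HuH-7-M, was computed in the same way from the No Probe spots and added after seeing the data. All 85 No Probe spots of each array lay above the BLANK limit. Differences are normalized log2 HuH-7-M minus HuH-7-P, and a log2 size of 1 (2-fold) was the fixed threshold of size. Because there is 1 array per group, no p-value was computed and directions are given only as higher or lower. For probes above background on 1 array only, a bound is given in place of a difference.

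The named miRNAs follow a rule fixed before the data were examined: the 10 highest and 10 lowest differences of at least 2-fold, the 5 brightest probes above background on each array only, the 5 brightest on each array, the 4 members with the largest difference in each of 13 lists, and miR-122-5p, miR-21-5p, miR-1246, miR-638, miR-663a, miR-3648 and miR-4258. The lists, also fixed then, were hepatocyte miRNAs, the let-7 family, the cluster of miR-17-5p and miR-92a-3p with its paralogs, the miR-200 family, miRNAs often raised in liver cancer, miRNAs described as tumour suppressors, miRNAs often bright on arrays of extracellular RNA, miRNAs known from the study, the chromosome 19 and chromosome 14 clusters, and miRNAs of blood, of endothelium and stroma, and of muscle and neural tissue. A list's median difference over its measured members is given with its percentile among 10000 random lists of the same size drawn from the same deciles of mean signal. This percentile describes the 2 arrays and is not a test of the cultures.

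The procedure was tested on simulated data with the 2565 probes at their measured mean signals, a spot noise of 0.13 (log2 SD) and 100 changed probes at each size of change. At a simulated 4-fold change 37.0% of 100 changed probes were called, 62.7% of the 59 above the No Probe limit and 100.0% of the 10 with a signal over 500. At a simulated 2-fold change 8.00% of 100 were called, 15.7% of the 51 above the No Probe limit and 38.5% of the 13 with a signal over 500. A simulated 2-fold change lies at the threshold itself, which limits its recovery at any brightness. The 4-fold results show that a 2-fold count from these arrays misses many dim probes. None of the unchanged probes was called, but both simulated arrays shared their mean signals and differed only in spot and BLANK noise. The simulation cannot show how many calls arise from differences in labelling, hybridisation or preparation.

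Alternatives fixed in advance were no background correction, subtraction of the BLANK mean, an offset of 16, scaling to the median or the 75th percentile of the measured miRNAs, scaling to the median of all probes, no scaling, cyclic loess, the authors' table, a BLANK limit of 3 SD, no filter, and thresholds of 1.5-fold and 3-fold. Added after seeing the data were scaling to the Spike Control spots, the background column, the No Probe limit and the table's names as given. Neighbouring miRNA genes were taken from the RefSeq gene table of the assembly GRCh38.p14, in which 739 of 788 miRNAs sought were matched by name; the sources used here name no build for the array, so no coordinates are given. Other computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.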

Results

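MicroRNA (miRNA) content was profiled in exosomes, small vesicles that cells release, from a pair of cultures of HuH-7, a human hepatocellular carcinoma cell line. The cultures were labelled HuH-7-P and HuH-7-M, and the labels do not spell out P and M. The series title places the work in the study of intrahepatic metastasis of liver cancer, and the comparison asks which miRNAs differ between the vesicles of the HuH-7-P and HuH-7-M cultures. RNA from the pelleted vesicles was labelled with Cy5 and hybridised to a 1-colour miRNA array, 1 array per culture, so no difference given here has a replicate and no test between the cultures could be made. Each array carried 2565 miRNA probes, and precision was limited by the number of arrays. Of these probes, 1669 on the HuH-7-P array and 1671 on the HuH-7-M array were above the limit set by 320 BLANK spots (65.1% on each), 1593 were above it on both arrays and 818 on neither. The limit was a signal of 62.3 on HuH-7-P and 61.2 on HuH-7-M. A second kind of control spot, labelled No Probe, was brighter than BLANK, with mean signals of 79.8 ± 7.20 on HuH-7-P and 81.1 ± 5.73 on HuH-7-M (SD over 85 spots of 1 array). Only 790 miRNAs exceeded the stricter limit drawn from the No Probe spots on both arrays, so many of the well-known miRNAs named below lay close to background.

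After quantile normalization with an offset of 50, steps that draw the arrays together, the exosome profiles of HuH-7-P and HuH-7-M resembled each other. With the BLANK mean subtracted and no offset, more miRNAs passed 2-fold (62 higher and 64 lower in HuH-7-M). A small set of miRNAs stood far apart. miR-300 and miR-381-3p, which are encoded in the large imprinted miRNA cluster of chromosome 14, and miR-5580-3p were more than 10-fold lower in HuH-7-M exosomes. miR-1246 and miR-1290, a pair often bright in vesicle RNA, had the highest HuH-7-M values relative to HuH-7-P among the miRNAs above background on both arrays, at 3.56-fold and 3.42-fold on the scale used here, which adds an offset of 50. In the authors' values, which carry no offset, miR-4800-3p (2.24 on the log2 scale) lay between miR-1290 (2.41) and miR-1246 (2.19). The hepatocyte miRNA miR-122-5p was dim on both arrays and differed by 0.41 on the log2 scale. On the scale with the offset, the members of the let-7 family, of the miR-200 family and of the lists of liver cancer miRNAs lay within 2-fold or were not above background on both arrays. Dim miRNAs of any list can stand further apart in the authors' values, as miR-21-5p does (-2.32).

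Among the 1593 miRNAs measured on both arrays, 7 were at least 2-fold higher and 27 at least 2-fold lower in HuH-7-M exosomes, and 1559 (97.9%) lay within 2-fold. The median log2 difference, HuH-7-M minus HuH-7-P, was 0.01, with quartiles of -0.07 and 0.10. Spots of 1 control probe on 1 array varied with a log2 SD of 0.12, so that a difference between 2 single spots carries a technical spread of 0.17. This within-array value leaves out any spread between cultures, and any between arrays from preparation, labelling, hybridisation or scanning. Spike Control 1 and 2, for example, differed between the arrays by 0.51 and 0.66 (BLANK-subtracted log2 ratio). The number and split of these calls depended on the background step and on how the arrays were scaled. With the same quantile normalization, subtraction of the BLANK mean without an offset gave 62 higher and 64 lower (49.2% higher), and an offset of 16 gave 16 and 39 (29.1%). Leaving out the background correction changed little, at 7 and 25 (21.9%). With the offset of 50, quantile normalization gave 20.6% of the calls as higher, against 45.5% (20 higher, 24 lower) after scaling to the median of the measured miRNAs, 43.5% (20 and 26) after scaling to the median of all probes, 55.1% (27 and 22) after scaling to the 75th percentile, 42.2% (19 and 26) without scaling, 23.7% (9 and 29) after cyclic loess and 2.67% (2 and 73) after scaling to the Spike Control spots. Correcting the background with the scanner's own background column instead gave 20 miRNAs higher and 18 lower, and kept 0 of the 7 higher and 1 of the 27 lower calls.

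**Figure D1:**
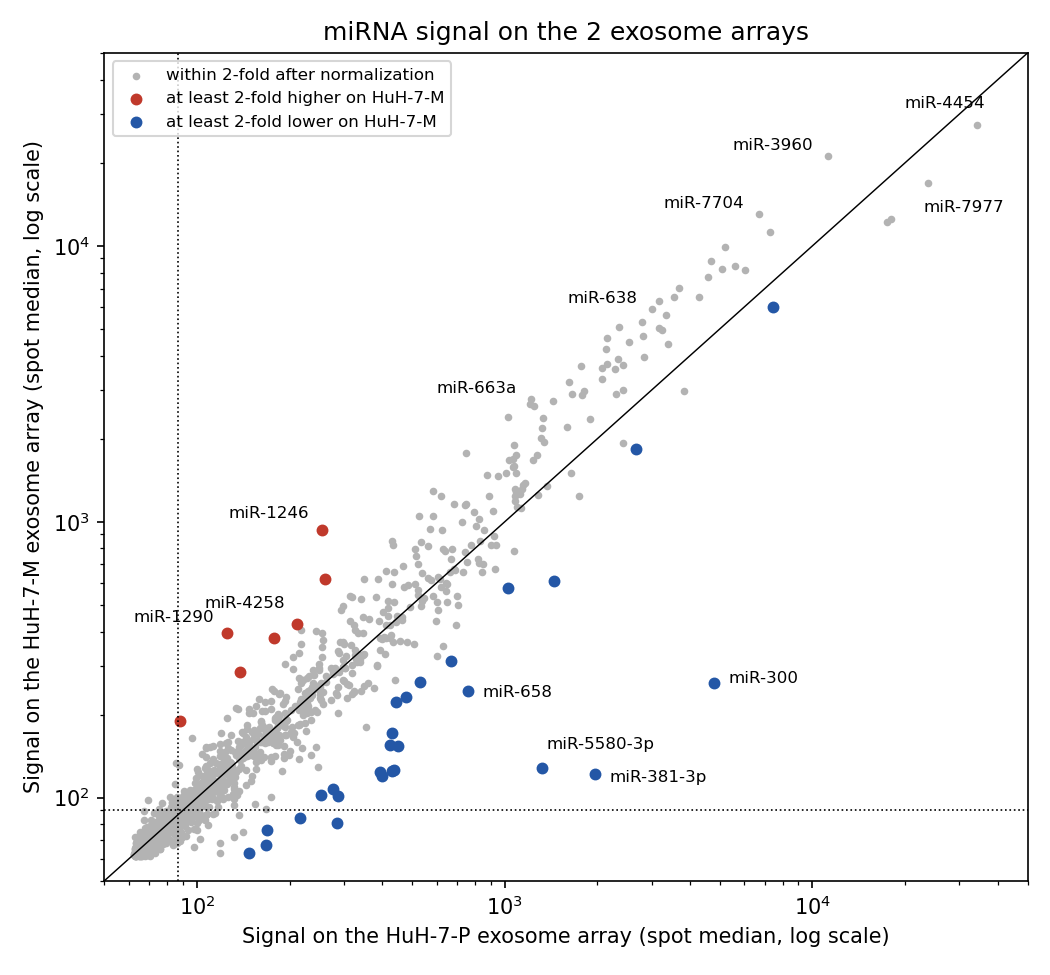
Each point is a miRNA above the BLANK limit on both arrays, with its spot signal on the HuH-7-P exosome array (x axis, log scale) and on the HuH-7-M exosome array (y axis, log scale). The solid line marks equal signal, dotted lines mark the No Probe limits (86.9 and 89.9), red points are the 7 miRNAs at least 2-fold higher on HuH-7-M and blue points the 27 at least 2-fold lower after quantile normalization. miR-300, miR-381-3p and miR-5580-3p lie far below the line, and most points with signals over 1000 lie above it.

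The lowest values in HuH-7-M exosomes were those of miR-300, with a signal of 4784 on HuH-7-P and 260 on HuH-7-M (normalized log2 difference -4.59), and of miR-381-3p, with 1960 and 122 (-4.40). miR-5580-3p read 1325 and 128 (-3.68). The remaining 7 of the 10 lowest ranged from -1.89 to -1.63: miR-4697-3p (signal 438 and 126), miR-7114-3p (429 and 125), miR-1296-3p (284 and 81.1), miR-9500 (399 and 119), miR-658 (762 and 243), miR-4684-3p (394 and 124) and miR-4685-5p (449 and 154). Of the 27 lower miRNAs, 22 were above the No Probe limit on both arrays, and miR-1296-3p was not. In the authors' values, which carry no added offset, the differences of miR-300 and miR-381-3p were -4.52 and -4.88, and dimmer probes moved further from 0, with miR-1296-3p at -3.29, miR-4697-3p at -2.47, miR-7114-3p at -2.45 and miR-4684-3p at -2.32.

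All 7 miRNAs that were at least 2-fold higher in HuH-7-M exosomes were above the No Probe limit on both arrays. miR-1246, a short RNA that can also derive from the U2 small nuclear RNA, had a signal of 255 on HuH-7-P and 932 on HuH-7-M (1.83). miR-1290 had 125 and 396 (1.77). The other 5 were miR-4732-5p (261 and 619, 1.26), miR-4800-3p (88.1 and 189, 1.23), miR-4730 (178 and 380, 1.20), miR-4648 (138 and 286, 1.12) and miR-4258 (212 and 424, 1.08). These 7 kept at least a 2-fold difference under each background correction, normalization and filter among the alternatives fixed in advance. With the background column, which is the plan read to the letter, 0 of the 7 did. After scaling to the Spike Control spots, which moves the median of all measured miRNAs to -0.58, all 7 stayed above 0, and only miR-1246 (1.33) and miR-1290 (1.17) stayed at least 2-fold higher.

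miR-638, miR-663a, miR-3648 and miR-4258 are known from the study, which chose them on these samples, so their direction here is not independent evidence. All 4 were brighter on the HuH-7-M array, at 3016 and 5881 for miR-638, 1218 and 2786 for miR-663a, and 1774 and 3657 for miR-3648. After quantile normalization 1 of the 4, miR-4258, was at least 2-fold higher, and miR-663a (0.69), miR-3648 (0.43) and miR-638 (0.28) lay within 2-fold. Their median of 0.56 (1.19 in the authors' values) lay at the 98.7th percentile of 10000 random lists matched on brightness, which describes these arrays only. Without scaling between the arrays the log2 differences were 0.97 for miR-638, 1.20 for miR-663a, 1.05 for miR-3648 and 1.04 for miR-4258. In the authors' values they were, in the same order, 1.01, 1.27, 1.10 and 1.30. After cyclic loess they were 0.48, 0.88, 0.67 and 1.05, and on the Spike Control scale 0.38, 0.62, 0.47 and 0.46. miR-638, miR-663a and miR-3648 lie at the bright end of the arrays, which quantile normalization shifted relative to no scaling, and miR-4258 does not. Before normalization, the 81 miRNAs with a signal over 1000 on both arrays had a median BLANK-subtracted log2 ratio of 0.63 and 84.0% of them were brighter on HuH-7-M, while 215 miRNAs of middle brightness had a median of 0.01 (quartiles -0.22 and 0.32). The Spike Control probes were also brighter on HuH-7-M, with a mean log2 ratio of 0.59.

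**Figure D2:**
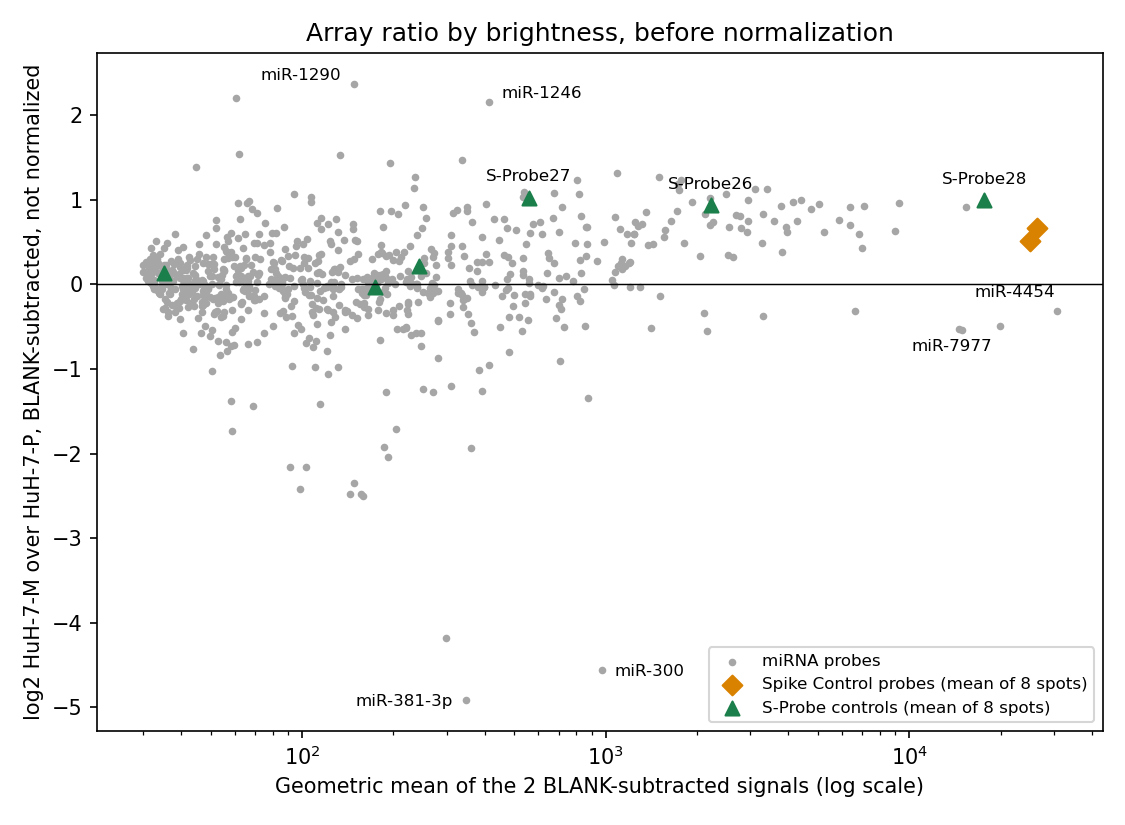
Each grey point is a miRNA above the No Probe limit on both arrays, with the geometric mean of its BLANK-subtracted signals (x axis, log scale) and its log2 ratio of HuH-7-M over HuH-7-P before normalization (y axis). Diamonds are the 2 Spike Control probes and triangles the 6 S-Probe controls, each the mean of 8 spots on each array; most miRNAs over 1000 lie above 0, and miR-4454 and miR-7977 at the bright end lie below it.

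The brightest probe on both arrays was miR-4454, with a signal of 34236 on HuH-7-P and 27509 on HuH-7-M. It was followed on HuH-7-P by miR-7977 (23726 against 16861), miR-7975 (18035 against 12476), miR-5100 (17530 against 12154) and miR-3960 (11232 against 21153). On HuH-7-M the next were miR-3960, miR-7977, miR-7704 (6711 on HuH-7-P, 13010 on HuH-7-M) and miR-7975. The 5 brightest probes held 18.1% of the summed signal of the miRNA spots on HuH-7-P and 13.8% on HuH-7-M. These sums include the BLANK background, so the shares are lower than they would be with it subtracted. After quantile normalization miR-3960 and miR-7704 were 0.92 and 0.89 higher, miR-7977, miR-7975 and miR-5100 were -0.36, -0.56 and -0.67, and miR-4454 was fixed at 0.00 because it ranks first on both arrays. These values depend on the scaling: after cyclic loess miR-3960 and miR-7704 were 0.14 and 0.29, and miR-7977, miR-7975, miR-5100 and miR-4454 were -1.33, -1.30, -1.29 and -1.25, past 2-fold lower. On the Spike Control scale the same 6 were 0.33, 0.37, -1.08, -1.11, -1.11 and -0.90, and without scaling miR-4454 was -0.32. The list of 34 miRNAs often bright on arrays of extracellular RNA was measured in full, with 2 members at least 2-fold higher (miR-1246 and miR-1290) and none lower, and with 26 above 0 and 6 below. Its median of 0.13 lay at the 93.8th percentile of random lists under quantile normalization, and was 0.67, above nearly all random lists, after scaling to the median of the measured miRNAs. miR-1915-3p, another member, read 585 and 1048 (0.70).

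Of 8 hepatocyte miRNAs, 5 were measured on both arrays and none differed by 2-fold, with a median of 0.06 at the 77.6th percentile. Without an offset the median was 0.39 with the BLANK mean subtracted and 0.34 in the authors' values, each at the 95.4th percentile, and on the Spike Control scale it was -0.53. miR-122-5p, the most abundant miRNA of normal liver, read 99.7 on HuH-7-P and 126 on HuH-7-M (0.41), miR-885-5p 89.6 and 95.6 (0.14), miR-194-5p 73.6 and 69.6 (-0.06) and miR-215-5p 67.0 and 68.0 (0.06). Scaling to the Spike Control spots, which moved the median of all measured miRNAs to -0.58, turned miR-122-5p to -0.19. The list lay at the 81.5th percentile on that scale. Only 1 of 9 let-7 probes was measured on both arrays, let-7e-5p, at 68.0 and 63.9 (-0.07). The cluster of miR-17-5p and miR-92a-3p and its paralogs, which promote proliferation, had 9 of 14 members measured, all within 2-fold on the scale with the offset, with a median of -0.01 at the 31.3rd percentile. Within it miR-17-5p (-0.36), miR-106a-5p (-0.30) and miR-20a-5p (-0.29) had the lower values and miR-92a-3p the highest (0.34). In the authors' values miR-17-5p (-1.04) and miR-20a-5p (-1.14) were past 2-fold, and miR-106a-5p was -0.90. The miR-200 family and miR-205, markers of the epithelial state, had 3 of 6 members measured, with a median of -0.04 at the 18.0th percentile (-0.19 with the BLANK mean subtracted and -0.42 in the authors' values), and miR-200c-3p read 114 and 108 (-0.05), miR-205-5p -0.04 and miR-200b-3p -0.03.

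Among 15 miRNAs often raised in liver cancer 8 were measured, none differed by 2-fold, and their median was 0.00 at the 45.3rd percentile (0.15 with the BLANK mean subtracted). miR-21-5p, often described as an oncogenic miRNA, read 97.9 on HuH-7-P and 66.2 on HuH-7-M (-0.60), with miR-221-3p at -0.28, miR-210-3p, which responds to hypoxia, at 0.29 and miR-130b-3p at 0.23. The miR-21-5p value was larger in size in the authors' values (-2.32), because its signal on HuH-7-M is close to the BLANK level. Of 20 probes for miRNAs described as tumour suppressors 7 were measured, without a 2-fold difference on this scale. Their median of -0.09 lay at the 0.465th percentile of random lists, and none of the 7 was above the No Probe limit on both arrays. miR-34a-5p, a target of p53, read 99.8 and 76.3 (-0.40), miR-16-5p 69.1 and 61.8 (-0.16), miR-26a-5p 67.6 and 61.5 (-0.12) and miR-22-3p was at 0.15. Without an offset these differences near the BLANK level were larger: the list median was -0.92 with the BLANK mean subtracted and -1.13 in the authors' values, where miR-34a-5p was -1.16, miR-16-5p -1.58 and miR-26a-5p -1.46. Under the stricter BLANK limit the list kept 4 members with a median of -0.014 at the 33.2nd percentile.

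The chromosome 14 cluster between DLK1 and DIO3 had 19 of 38 listed members measured, 2 of them at least 2-fold lower in HuH-7-M exosomes, miR-381-3p and miR-487b-3p (429 and 172, -1.32). miR-370-3p read 506 and 361 (-0.51) and miR-494-3p 140 and 159 (0.23). The median of the 19 was -0.02 at the 14.5th percentile (-0.097 in the authors' values), and most members were dim, since 4 of them exceeded the No Probe limit on both arrays, with a median of -0.92 at the 0.250th percentile. miR-300 lies in the same cluster and was not on the list. The chromosome 19 cluster, a primate miRNA cluster active in placenta, had 18 of 36 probes measured, none differing by 2-fold, with a median of -0.03 at the 6.53rd percentile (-0.15 in the authors' values). Its members with the larger differences were miR-524-5p (-0.24), miR-498 (206 and 171, -0.24), miR-520e (-0.21) and miR-521 (-0.10), and the 4 above the No Probe limit had a median of -0.13 at the 0.440th percentile.

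miRNAs typical of other cell types were dim on both arrays. Of 9 blood miRNAs 4 were measured, with a median of -0.02 at the 29.2nd percentile, and the erythroid miRNAs miR-451a (71.8 and 69.9, -0.01) and miR-486-5p (90.3 and 87.2, -0.03) and the leukocyte miRNAs miR-223-3p (-0.01) and miR-150-5p (-0.06) were near equal on the scale with the offset. In the authors' values miR-150-5p, close to the BLANK limit (66.3 and 62.8), was -0.66. There miR-451a was -0.08, and miR-486-5p and miR-223-3p were -0.07. Of 8 miRNAs of endothelium and stroma 3 were measured, with a median of 0.06 at the 75.1st percentile (0.24 in the authors' values), led by miR-214-3p (104 and 120, 0.25), with miR-199a-5p at 0.06 and miR-199b-5p at -0.01. Of 13 muscle and neural miRNAs 5 were measured, with a median of -0.17 at the 0.335th percentile, and of -0.79 in the authors' values. Without a filter on dim probes the median was -0.00087, no longer in the lowest 2.5% of random lists, and with the background column it turned to 0.0080. The muscle miRNA miR-206 was at least 2-fold lower (168 and 76.0, -1.21), while miR-133b (-0.19), miR-138-5p (-0.17) and the neural miR-124-3p (106 and 106, 0.06) were within 2-fold. Of these 5, only miR-124-3p exceeded the No Probe limit on both arrays.

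Above the BLANK limit on 1 array only were 78 miRNAs on HuH-7-M and 76 on HuH-7-P, for which the difference is a bound that holds on the scale it was computed on. After quantile normalization miR-27b-3p was at least 4.69-fold higher in HuH-7-M exosomes (signal 60.7 and 255) and miR-1197 at least 2.42-fold higher (54.7 and 137), against at least 3.12-fold and 1.63-fold on the Spike Control scale, and both exceeded the No Probe limit on HuH-7-M. The next on HuH-7-M were miR-582-3p at least 1.29-fold, miR-29b-3p at least 1.16-fold and miR-455-3p at least 1.10-fold higher, with signals of 76.9 or less. On the Spike Control scale these 3 bounds lay below 1-fold, so they do not hold there. On HuH-7-P only, miR-5186 was at least 2.16-fold (123 and 53.0), miR-4277 at least 1.87-fold, miR-3909 at least 1.47-fold, miR-382-3p at least 1.29-fold and miR-4650-5p at least 1.23-fold higher than on HuH-7-M. These bounds were larger on the Spike Control scale, in the same order 3.21, 2.84, 2.22, 1.92 and 1.85. Each bound sets the bright value against the higher of the lowest normalized value above background on the other array and the probe's own value there.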

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

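Of the tests below, those of neighbouring spots and of the second pixel column were set before their results were seen; those of the chromosome 14 cluster, of the brightness factor, of the control probes and of the brightness trend were chosen after.

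Signal outside the miRNA probes drew attention to 2 kinds of control spot and to the authors' table. Spots labelled No Probe had mean signals of 79.8 on HuH-7-P and 81.1 on HuH-7-M, above the BLANK limit on both arrays. Among the control probes above the No Probe limit, the BLANK-subtracted signal of HuH-7-M over HuH-7-P was 1.91 for S-Probe26, 2.03 for S-Probe27 and 1.99 for S-Probe28, and 1.43 and 1.59 for Spike Control 1 and 2. It was 1.16 for S-Probe21, 1.10 for S-Probe22 and 0.978 for S-Probe24. The single-spot probes gave 0.940 for S-Probe1001, 0.939 for S-Probe1004, 0.727 for S-Probe1007, 0.925 for S-Probe1014 and 1.15 for S-Probe1017. The sources used here do not say which RNA the S-Probe controls read. Of the rows with a value that the authors deposited, 1040 carried another name than the scanner output gives for the same value, and 71 of the 128 rows with at least a 2-fold difference were among them; the value of miR-5580-3p, for example, stood under miR-664b-3p.

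The first pattern is the more than 10-fold lower signal of miR-300, miR-381-3p and miR-5580-3p in HuH-7-M exosomes. A local mark on the HuH-7-P array is argued against by the 18 neighbouring miRNA spots, whose median log2 difference was 0.028 (range -0.42 to 0.50), while a misread spot area stays open: the 3 had a mean of -4.01 in the second pixel column, past its bound, but that column repeats the spot signal and decides nothing, as judged after the value was seen. An equal decrease of the whole chromosome 14 cluster is argued against for miR-300 and miR-381-3p. Near them, miR-487b-3p (-1.32) was past 2-fold lower but differed less than these 2. The neighbours miR-654-5p (-0.79), miR-1185-2-3p (-0.35), miR-1185-1-3p (-0.22) and miR-668-5p (0.19) differed far less. All 5 were above the No Probe limit. In the same cluster miR-1197 was above background on HuH-7-M only. A smaller or uneven decrease cannot be told apart. The 18 other listed members had a median of -0.016, but only 3 of them exceeded the No Probe limit (median -0.51, range -1.32 to 0.23). The bound set for that median was passed, and it was set aside after the values were seen because dim members near background can show no decrease; miR-5580-3p has no miRNA gene within 10 kb and is outside that explanation. miR-300 and miR-381-3p are close in sequence, so their probes may read 1 RNA, which was not tested, and a difference between the HuH-7-P and HuH-7-M cultures stays open and untested.

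The second pattern is that bright miRNAs were brighter on the HuH-7-M array before normalization. One brightness factor for the whole array, acting alone, is argued against. The 215 miRNAs of middle brightness had a median log2 ratio of 0.011 while the Spike Control probes had 0.59. On the Spike Control scale, which takes such a factor out, the median of all measured miRNAs was -0.58. A brightness factor together with less of most miRNAs on HuH-7-M therefore cannot be told apart. A steeper response of the HuH-7-M array at high brightness cannot be told apart from a difference in RNA: 4 bright control probes had a mean log2 ratio of 0.78 ± 0.23 (SD), at least the 0.63 of the 81 bright miRNAs, but S-Probe27, at signals of 451 and 853, had 1.02 against 0.09 for the 50 miRNAs nearest in brightness (10th to 90th percentile -0.39 to 0.74). Against a response shared by all bright spots, 4 of the 5 miRNAs with signals over 10000 on both arrays were lower on HuH-7-M (median -0.49). Whether these 4 probes read related RNA was not tested, so they may not be independent. Quantile normalization reduced the median of these 81 to 0.066 whatever the source, and miR-638, miR-663a and miR-3648 lie within 2-fold after it and near or above 2-fold without scaling.

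The third pattern is the higher signal of both miR-1246 and miR-1290 in HuH-7-M exosomes. The brightness trend as the whole cause is argued against by its size. Without scaling, miR-1246 and miR-1290 differed by 1.91 and 1.75. The 81 bright miRNAs had a median of 0.62 there (quartiles 0.26 and 0.83), and neither miR-1246 nor miR-1290 was among them. Both exceed that upper quartile by more than the technical spread of 0.17, though that spread covers spots of 1 array only. Cyclic loess reduced the median of the 81 to 0.23 and left miR-1246 and miR-1290 at 1.86 and 1.76. That result decides nothing, because both probes were dimmer than the 81 and loess had little trend to remove there. A local mark is argued against by the 16 neighbouring spots, whose median was 0.00041 (range -0.18 to 0.28). The probes' sequences are related, so they may read fragments of a shared RNA, and carry-over of other RNA into the pellet was not tested. With 1 array per culture, a difference between the cultures and a difference between preparations remain open.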

How the results depend on the processing

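No paired analysis was possible because each group has 1 array. No replicate could be left out for the same reason. Settings added after seeing the data were Spike Control scaling, the background column, the No Probe limit and the table's names as given. One limit is the number of arrays, and another is signal over background: 790 miRNAs exceeded the No Probe limit on both arrays, against 1593 above the BLANK limit. Each background correction, normalization and filter among the alternatives fixed in advance kept all 7 higher calls of the main setting. Of the 27 lower calls each kept between 22 and 27, although the authors' table holds no matched row for 1 of the 27. With the background column, which is the plan read to the letter, 0 of the 7 and 1 of the 27 were kept. Counts, higher then lower, were 62 and 64 with the BLANK mean subtracted, 62 and 66 in the authors' values matched to their probes, 16 and 39 with an offset of 16, 20 and 24 with the median of measured miRNAs, 27 and 22 with the 75th percentile, 20 and 26 with the median of all probes, 19 and 26 without scaling, 9 and 29 with cyclic loess, 2 and 73 with Spike Control scaling (26 of the 27 lower kept), 20 and 18 with the background column, 45 and 54 at 1.5-fold and 2 and 11 at 3-fold. The counts were 7 and 25 without background correction, 7 and 27 with the BLANK limit of 3 SD and 9 and 28 without a filter on dim probes. Subtraction without an offset gives more calls because the offset shrinks differences of dim probes. The causes of the other differences between settings were not tested.

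Of 172 list medians under an alternative, 152 stayed inside or outside the outer 2.5% of random lists at either end, as in the main setting, without moving across 0 by more than the technical spread, and 3 more stayed so but moved across 0 by more than it; of the 152, 138 kept their sign and 14 changed it, the latter reaching at most 0.035 in size. The 3 are the moves under Spike Control scaling of hepatocyte miRNAs to -0.53, liver cancer miRNAs to -0.59 and endothelium and stroma to -0.54, as it moved the median of all miRNAs to -0.58. The list of tumour suppressors was larger in size without an offset, at -0.92 with the BLANK mean subtracted and -1.13 in the authors' values. Tumour suppressors left the lowest 2.5% of random lists at 3 SD (-0.014), without a filter (-0.0028) and with the background column (-0.010), as did muscle and neural miRNAs without a filter (-0.00087); the latter turned to 0.0080 with the background column. The extracellular list entered the highest 2.5% at 0.67 with the median of measured miRNAs, 0.73 with the 75th percentile, 0.67 with all probes, 0.66 without scaling, 0.70 in the authors' values, 0.36 under the table's names as given, 0.082 with Spike Control scaling and 0.034 with the background column. The study's 4 miRNAs turned to -0.084 with the background column. Above the No Probe limit the chromosome 19 list reached -0.13 and the chromosome 14 list -0.92, and blood miRNAs without a filter reached the lowest 2.5% at -0.011.

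With the background column 9 named miRNAs reversed: miR-1246 (-0.41), miR-1290 (-0.027), miR-300 (0.66), miR-381-3p (0.077), miR-4697-3p (0.029), miR-658 (0.10), miR-4684-3p (0.044), miR-4685-5p (0.054) and miR-206 (0.0080). That column carries the spot's own signal, with the same sign of difference in 34 of the 34 calls of at least 2-fold (r = 0.98 across these probes), so subtracting it takes the difference away. Under the table's names as given, which pair these names with other values, 5 reversed: miR-4732-5p (-0.40), miR-4730 (-0.51), miR-7114-3p (0.39), miR-1296-3p (0.087) and miR-4684-3p (0.25).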

Other observations

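The following miRNAs were chosen after their values were seen. miR-27b-3p was at least 4.69-fold higher in HuH-7-M exosomes after quantile normalization and at least 3.12-fold on the Spike Control scale, while of the miRNAs encoded beside it miR-23b-3p, below the No Probe limit, read 86.3 on HuH-7-P and 82.1 on HuH-7-M (-0.04) and miR-24-3p, which is also made from another locus, 326 and 329 (0.02). Its close relative miR-27a-3p read 65.7 and 61.2 (-0.08), near the BLANK limit on both arrays. Around miR-300 and miR-381-3p on chromosome 14, miR-487b-3p (-1.32) and miR-654-5p (-0.79) were lower in HuH-7-M exosomes, miR-1185-1-3p (-0.22) and miR-1185-2-3p (-0.35) less so, and miR-668-5p was 0.19. In the same cluster miR-1197 was above background on HuH-7-M only, at least 2.42-fold higher after quantile normalization (1.63-fold on the Spike Control scale), and miR-382-3p on HuH-7-P only, at least 1.29-fold higher there. The related miRNAs miR-500a-3p (131 and 72.0, -0.93) and miR-502-3p (118 and 68.5, -0.85) were both lower in HuH-7-M exosomes, and neither exceeded the No Probe limit on HuH-7-M.

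A hypothesis, set with its test before the result was seen, was that differences follow the precursor or the genomic cluster of a miRNA. Across 129 pairs of arms of one hairpin, both above the No Probe limit on both arrays, the correlation of the log2 differences was 0.012, inside the central 95% of random pairings (-0.17 to 0.18), and 58.1% of the pairs had the same sign. That meets the bound set for no relation. Many of these differences are no larger than the technical spread of 0.17, so the correlation alone cannot decide. In pairs with 1 arm past 2-fold, such as miR-4697 (3p -1.89, 5p 0.36), miR-4685 (5p -1.63, 3p 0.13) and miR-4800 (3p 1.23, 5p 0.19), the other arm lay within 2-fold. In those pairs the difference was not shared. Across 56 pairs of miRNAs whose genes lie within 10 kb the correlation was 0.28, at the 96.9th percentile of random pairings (central 95% from -0.19 to 0.29), and 55.4% of the pairs had the same sign. That value meets the bound set in advance for no relation, but lies so near its edge that it decides nothing, a reading made after the value was seen. The pairs share miRNAs, and the pair of miR-300 (-4.59) and miR-381-3p (-4.40) has by far the largest values, so the correlation may rest on those probes. Pairs are not independent replicates, and nothing here tests the cultures.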
